A study of Mus musculus with 13 samples.

How the data were processed

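RNA-seq of mouse splenic B cells was analysed in 13 libraries, 4 from control unstimulated cells and 3 from each of the other groups. The authors deposited read counts per gene symbol for each library, and the submitters' processing notes name TopHat, HTSeq and the mm10 genome build, with no versions. The authors also deposited log2 values for each library, for which the submitters' processing notes name DESeq2. Their exact transformation is not given in the sources used here. Gene annotation, strand setting and multi-mapping rule of the counting are likewise not given in the sources used here. Per the labels' protocols, RNA was taken with TRIzol and cleaned on columns, and B cells were selected by removing CD43-bearing cells, which also removes B-1 and plasma cells. Labels number the libraries within groups but do not say that each is a separate animal; where they are not, p-values measure only the spread between these samples.

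The count tables held 23337 gene symbols, and 1 with a missing cell was left out. Reads were present for 18872. The log2 tables held 20945 symbols, and on the more abundant genes their values followed the log2 counts with a slope of 0.998 to 1.00. GENCODE vM21 (mm10) gene names matched 97.9% of symbols and gave the coordinates. Replicates were compared before averaging: chi-square per gene lay between 8.69 and 38.7, so no pair of libraries agreed within sampling noise. Totals per library were 21407724 to 33244755 counts, and 3 counts in a library stood for 0.0902 to 0.140 CPM. Intervals and floors cover counting error only.

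Counts were tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr by group (minimum count 10), TMM factors and a quasi-likelihood fit with robust estimation of all 13 libraries with a mean per group. This left 13574 genes and 9 residual degrees of freedom, with a common biological coefficient of variation of 0.175. Standard errors are the log2 fold change divided by the root of the F statistic. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Levels are TMM-normalized CPM, given as mean ± SD. Comparisons were deficient against control in each state, stimulated against unstimulated in each genotype, and the difference of the stimulation responses. The samples in each group, tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

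Of 34 gene lists, covering B cell functions, signalling and the other cell types of the spleen, 31 were tested with limma 3.58.1 camera on log-CPM values (prior count 2) at a preset inter-gene correlation of 0.01, adjusted over the 31 lists of a comparison. Camera with an estimated correlation called 0 lists in every comparison, and fry called 3, 3, 20, 20 and 0. The immunoglobulin constant and mitochondrially encoded lists had no matching rows, and the sex-linked list was used only to read the sex of each library. Of 590 list members 560 matched a row. Markers of T, NK, myeloid, dendritic, platelet and stromal cells, and the germinal centre, marginal zone, transitional, B-1 and neutrophil lists were not called in any of the 5 comparisons with all 13 libraries and no block or covariate.

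The genes named were Zc3h12a and, for each comparison between groups, the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 2 and no overlap between groups, leaving out immunoglobulin and T cell receptor segments and predicted gene models. For the difference of responses the rule took the 5 largest of each sign without the overlap condition, and for each list described up to 4 members with the smallest p. The genes named for the blocked difference of responses, and Slit3, were chosen after their values were seen. Some genes that the rule takes are not reported here.

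Reads shared by overlapping genes cannot be separated without a stated strand setting, so the levels of such genes are uncertain. Among the genes named, B3gnt8 overlaps Bckdha over 5155 bases, Cxcl10 lies within Art3 (2252 bases), Spns2 overlaps Mybbp1a over 131 bases and Eng overlaps Fpgs over 61 bases. Adm, Bcl2, Cables1, Ebi3, Fcgr2b, Pou2f2, Rasgrp2 and Tnfrsf18 have noncoding RNAs annotated on the opposite strand.

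Library numbers were checked for pairing. Deviations from the group means of same-numbered libraries of the same genotype in both states correlated with r of 0.73, 0.49 and 0.57 in control and 0.83, 0.76 and 0.62 in deficient cells, across 9658 genes, so numbers pair the states within each genotype. The animal as a block then left 4 residual degrees of freedom.

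Alternatives were DESeq2's size factors and upper-quartile factors in edgeR, DESeq2 1.42.0, no filter and a stricter one (1 CPM in 3 libraries), only the groups compared, the replicate block, sex as a term, a minimum fold of 1.5, limma on the deposited log2 values, and leaving out each library in turn. Leaving out both libraries of deficient animal 1 and an erythroid marker level as a term were added after the data were seen. Self-tests drew independent counts for all 13 libraries from the control unstimulated means, with 200 genes changed by known folds in 1 group. For a fold of 2 the test recovered 62.7% in the unstimulated genotype comparison (13221 genes), 64.2% in the stimulated one (13219), 64.2% and 59.7% for stimulation in control (13220) and deficient cells (13245), and 61.2% for the difference of responses (13230). Shares of false calls were 3.5%, 2.4%, 9.9%, 4.4% and 4.2%. Far more genes were called for real stimulation, and the real libraries pair by number across states. The shares recovered and false thus do not carry over to stimulation or to the difference of responses. A list shifted by a log2 of 0.3 was called in each simulated comparison, and 0 to 2 of 100 unshifted lists were. The simulated genes varied independently, so this does not check the preset correlation of 0.01 on real lists. Estimated correlations were 0.63 for cell cycle, 0.70 for interferon response, 0.75 for cholesterol synthesis and 0.78 for ribosome biogenesis genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.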

Results

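The data are RNA-seq read counts per gene from mouse splenic B cells, isolated by removing CD43-bearing cells with magnetic beads, in 13 libraries. Deficient cells carried floxed alleles of Zc3h12a, the gene for the RNA-degrading enzyme Regnase-1, together with a B cell Cre recombinase that tamoxifen activates, and control cells carried the same Cre with intact alleles. Each genotype was profiled unstimulated and after 4 h of stimulation through the B cell receptor (BCR), giving 4 control unstimulated, 3 deficient unstimulated, 3 control stimulated and 3 deficient stimulated libraries. The labels as read here give no time for the unstimulated libraries, so changes after stimulation may include those of 4 h in culture. The comparisons ask what the loss of Regnase-1 changes in resting B cells, what it changes in stimulated B cells, and whether the response to the receptor differs between genotypes.

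Library totals lay between 21407724 and 33244755 counts. Control unstimulated libraries 1 to 4 held 27007868, 28656506, 27035246 and 28552647 counts. Deficient unstimulated libraries 1 to 3 held 32078095, 31647917 and 21407724 counts. Control stimulated libraries held 33032469, 29604013 and 28309960 counts, and deficient stimulated libraries 22638210, 33244755 and 25417496 counts. At these depths 3 counts corresponded to 0.0902 to 0.140 CPM, the count scaled to the library total. Stimulation separated the libraries on the first principal component, which held 81.1% of the variance. The second held 7.91%, and both libraries of deficient animal 1 lay at its negative end, at -22.6 unstimulated and -25.9 stimulated.

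Zc3h12a (chromosome 4, 125118423 to 125127840, minus strand, mm10) was measured first in every library. Its TMM-normalized level was 124, 131, 121 and 124 CPM in control unstimulated libraries 1 to 4 and 89.2, 99.6 and 111 CPM in deficient unstimulated libraries 1 to 3. It was 157, 156 and 147 CPM in the control stimulated libraries and 92.6, 103 and 113 CPM in the deficient stimulated libraries. All deficient libraries lay below all control libraries of the same state. The log2 difference was -0.32 ± 0.07 (SE) in unstimulated cells, which did not pass edgeR's quasi-likelihood test (adjusted p = 0.106). In stimulated cells it was -0.58 ± 0.08 (adjusted p = 0.000784). Reads from exons outside the deleted part remain in a floxed gene, so this level checks the genotype labels only in part. The unstimulated difference passed the threshold in DESeq2 (adjusted p = 0.0175), with sex as a term (adjusted p = 0.00848) and without deficient unstimulated library 3 (adjusted p = 0.0372).

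**Figure D1:**
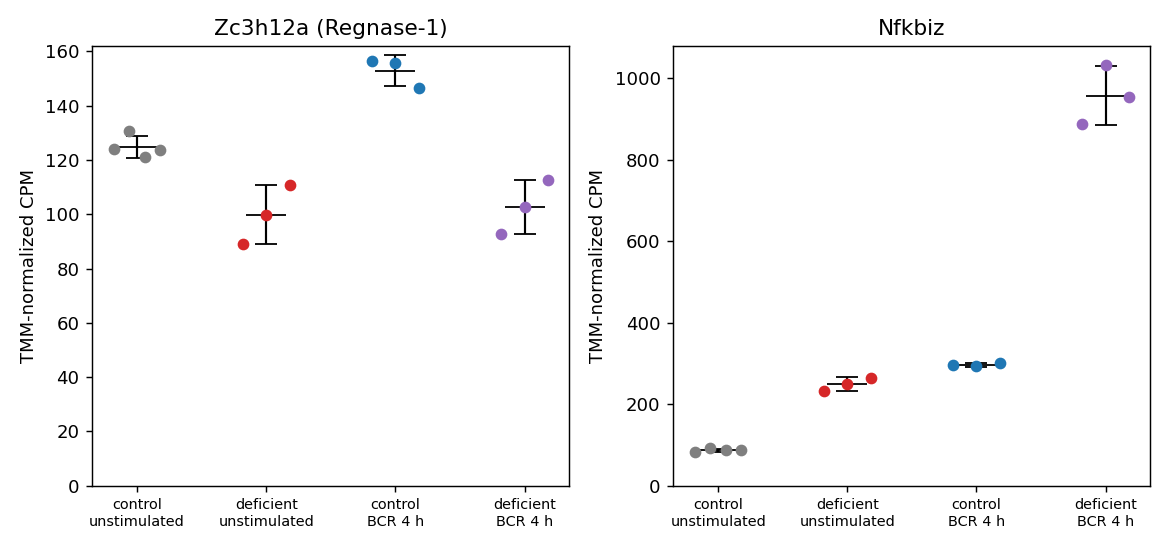
TMM-normalized CPM of Zc3h12a (left) and Nfkbiz (right) in each of the 13 libraries, one point per library, with the group mean and SD as bars. Deficient libraries lie below control libraries for Zc3h12a and above them for Nfkbiz in both states, with Nfkbiz means of 87.4, 249, 297 and 958 CPM from left to right.

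In unstimulated cells Nfkbiz, which encodes the atypical NF-kB regulator IkBz, was 2.85-fold higher in deficient than in control cells, at 249 ± 16.7 CPM (SD, n = 3) against 87.4 ± 3.78 CPM (n = 4). Other genes that rose were Pou2f2, a B cell octamer-binding transcription factor, the pro-apoptotic gene Bmf, the inhibitory Fc receptor gene Fcgr2b, the AP-1 family gene Batf, and Zc3h12d, a paralog of Zc3h12a. Pou2af1, the coactivator of Pou2f2, fell from 1255 ± 82.1 to 777.5 ± 53.0 CPM. The AP-1 gene Fos, the TGF-beta coreceptor gene Eng and the transcription factor gene Zbtb46 also fell.

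edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 44 of 13574 genes, 17 higher and 27 lower in deficient cells, of which 3 rose and 1 fell by more than 2-fold. Log2 changes were 1.51 ± 0.06 (SE) for Nfkbiz (chromosome 16, 55811375 to 55838899; adjusted p = 2.7e-09), 0.69 ± 0.07 for Pou2f2 (adjusted p = 9.7e-05) and 0.84 ± 0.09 for Bmf (adjusted p = 0.00104). They were 1.13 for Cdk5rap1, 0.86 for Krt222, 0.57 for Zc3h12d, 0.54 for Fcgr2b and 0.53 for Batf. Among genes that fell, the changes were -1.26 ± 0.22 for Eng (chromosome 2, 32646595 to 32682669; adjusted p = 0.0374), -0.85 for Zbtb46, -0.79 for Cables1, -0.76 for Fos and -0.72 for Rnf125, which encodes a ubiquitin ligase. They were -0.70 for Snrnp25, -0.69 ± 0.07 for Pou2af1 (chromosome 9, 51213708 to 51240080; adjusted p = 0.000238) and -0.54 for Cdk5r1. All 44 called genes had no overlap between the groups, against 8.72% of all tested genes and 2 of 35 orderings by chance. With DESeq2's size factors the split was 21 higher and 20 lower, and with upper-quartile factors it was 36 and 34. The count was 27 without control library 1, 18 without control library 3, 29 without control library 4, 27 without deficient library 1 and 17 without deficient library 2, and it was 198 with sex as a term, 75 with the erythroid marker level as a term, 74 without both libraries of deficient animal 1, 163 in DESeq2 and 2 against a minimum fold of 1.5. Single libraries also decided some calls: without deficient library 2 the adjusted p was 0.213 for Eng, 0.163 for Cdk5r1, 0.163 for Zc3h12d, 0.158 for Rnf125, 0.105 for Fcgr2b and 0.0702 for Zbtb46. It was 0.108 for Krt222 without deficient library 1 and 0.117 for Cdk5rap1 without control library 1, and each of these calls also ended without at least 1 other library. With the replicate number as a block the calls of Zc3h12d, Fcgr2b, Eng and Cdk5r1 ended as well.

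Immediate early genes, which cells switch on within minutes of a signal, lay lower in unstimulated deficient cells (camera, adjusted p = 7.7e-12; adjusted p = 0.374 with an estimated correlation). Of 22 members 0 rose, 3 fell and 19 were not called, or 8 fell when adjusted over the list alone, with a median log2 change of -0.32. Deficient library 1 had the lowest summed level, 2003 CPM against 2307 and 2442 CPM in the other deficient libraries and 2564 to 2880 CPM in the control libraries, and without both libraries of deficient animal 1 the median was -0.21 (adjusted p = 1.5e-09). Junb fell by 0.52, Fos by 0.76 and Dusp1 by 0.47 on the log2 scale, and Dusp5, at -0.50, did not pass. Activation surface genes were also lower (adjusted p = 0.000908; adjusted p = 0.528 with an estimated correlation), with 2 of 22 members falling, Il21r (-0.32) and Tnfrsf1b (-0.28), or 7 falling and 1 rising when adjusted over the list alone. The NF-kB feedback list was lower on balance (adjusted p = 0.0129; adjusted p = 0.811 with an estimated correlation; median -0.15), although the 2 members called, Nfkbiz and Tnfaip8 (0.35), rose, and 2 rose and 10 fell when adjusted over the list alone. This call ended without deficient library 1 (adjusted p = 0.178) and without deficient animal 1 (adjusted p = 0.238, median -0.10). The resting B cell list was lower (adjusted p = 0.0193; adjusted p = 0.811 with an estimated correlation; median -0.13) with 0 of 20 members called, the same over the list alone, Cdkn1b at -0.21 and Tsc22d3 at -0.27, and its call ended without deficient library 1 (adjusted p = 0.178), deficient library 2 (adjusted p = 0.0836) or deficient animal 1 (adjusted p = 0.158, median -0.050).

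Higher lists in unstimulated deficient cells were cholesterol synthesis, cell cycle and known Regnase-1 targets. Cholesterol synthesis genes had a median log2 change of 0.16 (adjusted p = 4.2e-05; adjusted p = 0.895 with an estimated correlation), with 0 of 20 members called, the same over the list alone, and 19 above 0, such as Mvk at 0.33 and Idi1 at 0.34. The summed levels overlapped, at 1465 to 1895 CPM in control and 1471, 1978 and 1873 CPM in deficient libraries 1 to 3, and without both libraries of deficient animal 1 the median was 0.27 (adjusted p = 3.8e-09). Cell cycle genes had a median of 0.37 (adjusted p = 9.0e-05; adjusted p = 0.895 with an estimated correlation), again with 0 of 30 members called over all genes or over the list alone, such as Tyms at 0.70. That call ended without deficient library 1 (adjusted p = 0.935). With sex as a term the median was 0.60. The summed erythroid marker level moved with it: 1552 CPM in deficient unstimulated library 1 against 235 and 898 CPM in the other deficient libraries and 412 to 895 CPM in the control libraries. Regnase-1 targets were called higher (adjusted p = 0.0443; adjusted p = 0.528 with an estimated correlation) with a median of -0.03 and a mean of 0.09, since 1 of 18 members rose, Nfkbiz, the same over the list alone. That call ended without control library 1 (adjusted p = 0.124), control library 2 (adjusted p = 0.0957), deficient library 1 (adjusted p = 0.180), deficient library 3 (adjusted p = 0.0548) or deficient animal 1 (adjusted p = 0.173, median 0.047). With sex as a term the median was 0.14 (adjusted p = 0.00734).

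Markers of other cell types also varied between libraries. Myeloid markers summed to 505, 511, 939 and 863 CPM in control unstimulated libraries 1 to 4 and to 1034, 619 and 495 CPM in deficient unstimulated libraries 1 to 3. Neutrophil markers summed to 37.7, 102, 254 and 447 CPM in the control and 454, 78.2 and 63.2 CPM in the deficient libraries. With all 13 libraries neither list was called (adjusted p = 0.406, median -0.13, and adjusted p = 0.899, median -0.74). Without both libraries of deficient animal 1 both were called lower in unstimulated deficient cells, myeloid markers at a median of -0.84 (adjusted p = 0.000197) and neutrophil markers at -1.63 (adjusted p = 0.0311). With sex as a term neutrophil markers were instead called higher, at a median of 0.20 (adjusted p = 0.00365). Myeloid markers were not called with it, at 0.060 (adjusted p = 0.410). The direction of the neutrophil call thus depended on the setting, while myeloid markers were called only as lower. Erythroid markers, not called without sex as a term (adjusted p = 0.421, median 0.49), were called higher with it (adjusted p = 0.00253, median 0.87). Deficient animal 1 was the only deficient female, so the sex term does not separate sex from that animal. Estimated correlations were 0.55, 0.85 and 0.95 for myeloid, neutrophil and erythroid markers. Camera with these, run only on all 13 libraries without added terms, gave adjusted p of 0.895, 0.958 and 0.895.

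**Figure D2:**
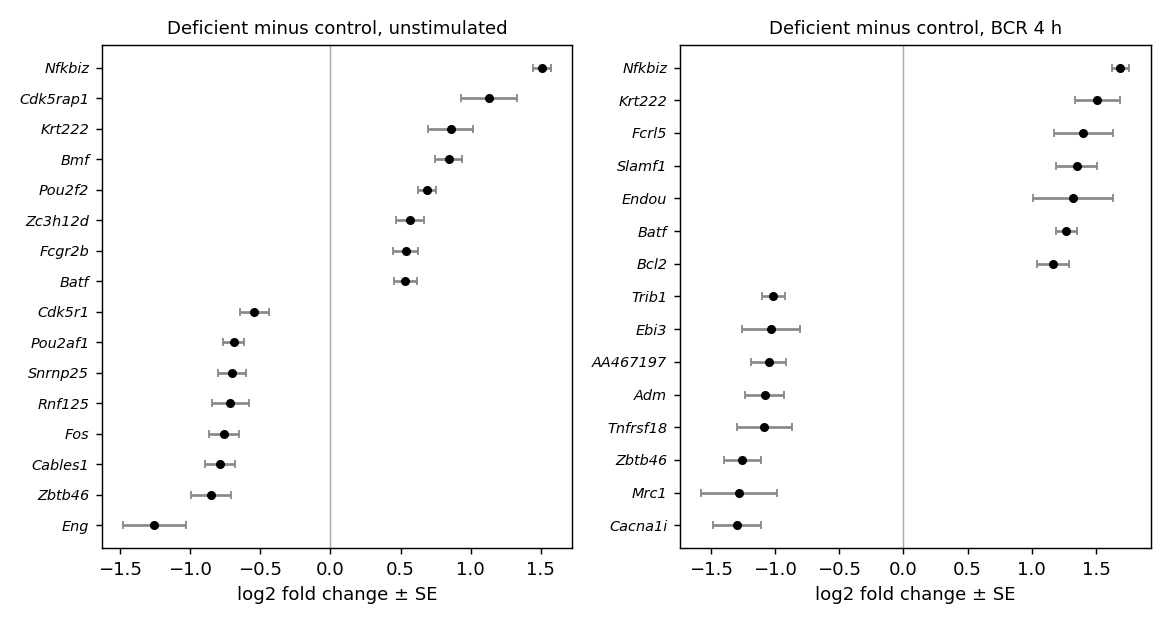
Log2 fold change of deficient against control cells, with standard errors, for the 8 largest rises and 8 largest falls among the genes that met the naming rule, in unstimulated (left) and BCR-stimulated (right) cells, with 1 of the stimulated rises not reported here. Nfkbiz lies highest in both states, at 1.51 and 1.69, and Zbtb46 lies among the falls in both.

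After 4 h of BCR stimulation Nfkbiz was 3.22-fold higher in deficient than in control cells, at 958 ± 72.7 CPM (SD, n = 3) against 297 ± 4.55 CPM (n = 3). Batf rose 2.41-fold, from 50.2 ± 4.13 to 121 ± 7.11 CPM, and the anti-apoptotic gene Bcl2 rose 2.24-fold, from 15.1 ± 2.11 to 33.9 ± 4.19 CPM. The surface receptor genes Slamf1 and Fcrl5 rose 2.55-fold and 2.64-fold. The adhesion molecule gene Icam1 fell from 245 ± 0.367 to 128 ± 10.5 CPM, and Trib1, which encodes a pseudokinase, fell from 94.8 ± 9.03 to 47.1 ± 3.66 CPM.

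The same test called 273 of 13574 genes, 102 higher and 171 lower, of which 15 rose and 12 fell by more than 2-fold. Log2 changes were 1.69 ± 0.07 (SE) for Nfkbiz (adjusted p = 1.8e-09), 1.27 ± 0.08 for Batf (chromosome 12, 85686669 to 85709087; adjusted p = 6.6e-07), 1.17 ± 0.12 for Bcl2 (chromosome 1, 106538178 to 106714274; adjusted p = 8.2e-05) and 1.35 ± 0.16 for Slamf1 (adjusted p = 0.000242). They were 1.51 for Krt222, 1.40 for Fcrl5 and 1.32 for Endou. The falls were -1.29 ± 0.19 for Cacna1i, a voltage-gated calcium channel gene (chromosome 15, 80287238 to 80398279; adjusted p = 0.00284), -1.28 for Mrc1, the macrophage mannose receptor gene, and -1.25 for Zbtb46. They were -1.08 for Tnfrsf18, -1.08 for Adm, -1.05 for AA467197, -1.03 for Ebi3, an interleukin subunit gene, and -1.01 ± 0.09 for Trib1 (adjusted p = 2.2e-05). All 273 called genes had no overlap between the groups, against 17.84% of all tested genes and 10% by chance. The count was 129 without control library 1, 180 without control library 3 and 177 without deficient library 2. It was 511 with sex as a term, 532 in DESeq2 and 12 against a minimum fold of 1.5. Leaving out single libraries also ended the calls of Mrc1 (adjusted p up to 0.159, without control library 3), Endou (0.155, without deficient library 2), Ebi3 (0.155, without deficient library 1), Fcrl5 (0.0557, without control library 1) and Tnfrsf18 (0.0622, without control library 3).

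Immediate early genes lay lower in stimulated deficient cells as well (adjusted p = 4.1e-13; adjusted p = 0.288 with an estimated correlation; median -0.45). Of 22 members 0 rose, 5 fell and 17 were not called, or 15 fell and 1 rose when adjusted over the list alone. Dusp5 fell by 0.79, Id3 by 0.67, Dusp1 by 0.59 and Junb by 0.41 on the log2 scale. In the activation surface list (adjusted p = 0.000712; adjusted p = 0.520 with an estimated correlation; median -0.12), 3 of 22 members fell, Icam1 (-0.93), Il21r (-0.42) and Il4ra (-0.38), and 2 rose, among them Slamf1, with 5 falling and 2 rising when adjusted over the list alone. RNA decay regulators were lower (adjusted p = 0.000712; adjusted p = 0.659 with an estimated correlation; median -0.11) with 2 of 15 falling, Zfp36 (-0.52) and Zfp36l1 (-0.64), which encode proteins that destabilize mRNA, or 4 falling and 1 rising when adjusted over the list alone. Cytokine genes were lower (adjusted p = 0.0319; adjusted p = 0.659 with an estimated correlation; median -0.12) with 3 of 24 falling, Ltb (-0.48), Tgfb1 (-0.33) and Ebi3, or 4 when adjusted over the list alone. That call ended without control library 3 (adjusted p = 0.228), without deficient library 3 (adjusted p = 0.212) or with sex as a term (adjusted p = 0.122). Without deficient animal 1 the median was -0.24 (adjusted p = 0.0102). The resting B cell list was lower (adjusted p = 0.0319; adjusted p = 0.659 with an estimated correlation; median -0.08) with 0 of 20 called, or 1 rising and 1 falling when adjusted over the list alone. Its call ended without control library 1 (adjusted p = 0.112), control library 3 (adjusted p = 0.0881) or deficient library 2 (adjusted p = 0.0695).

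Interferon response genes lay higher in stimulated deficient cells, with all 25 members above 0 but 0 called over all genes or adjusted over the list alone (adjusted p = 0.000712; adjusted p = 0.955 with an estimated correlation; median 0.26). Gbp3 was at 0.54 and Stat2 at 0.40, and the call ended without control library 1 (adjusted p = 0.0981) or control library 2 (adjusted p = 0.0773). The list summed to 2457, 2322 and 3979 CPM in control stimulated libraries 1 to 3 and to 4012, 3316 and 2884 CPM in the deficient ones, so the groups overlapped, and without deficient animal 1 the median was 0.09 (adjusted p = 0.0384). Control library 3 and deficient library 1 also stood highest in myeloid markers, at 632 CPM against 444 and 390 CPM in the other control libraries and 687 CPM against 502 and 463 CPM in the other deficient libraries. They stood highest in neutrophil markers as well, at 176 CPM against 28.2 and 73.8 CPM and at 312 CPM against 44.9 and 46.2 CPM. Cholesterol synthesis genes were higher (adjusted p = 0.000712; adjusted p = 0.955 with an estimated correlation; median 0.15) with 1 of 20 rising, Dhcr7 (0.46), the same when adjusted over the list alone, and the call ended without control library 1 (adjusted p = 0.112). The summed levels overlapped here too, at 3440 to 4348 CPM in control and 3602 to 4315 CPM in deficient stimulated libraries. Glycolysis genes were higher (adjusted p = 0.00639; adjusted p = 0.535 with an estimated correlation; median 0.09) with 0 of 24 called, the same over the list alone, Tpi1 at 0.26, and the call ended without control library 1 (adjusted p = 0.0511). Cell cycle genes had a median of 0.47 (adjusted p = 0.00861; adjusted p = 0.955 with an estimated correlation), although the 1 of 30 members called, Ccnd2, fell (-0.69), the same when adjusted over the list alone. That call ended without control library 1 (adjusted p = 0.0596), control library 3 (adjusted p = 0.0881) or deficient library 1 (adjusted p = 0.992). Erythroid markers summed to 1404 CPM in deficient stimulated library 1 and to 159 and 560 CPM in the other deficient stimulated libraries.

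Members of lists that were not called as a whole also changed in stimulated deficient cells. Known Regnase-1 targets were not called there (camera, adjusted p = 0.784, and 0.955 with an estimated correlation). Their median log2 change was -0.04, and 8 of 18 members lay above 0. Of these members 1 rose, Nfkbiz, and 17 were not called, the same adjusted over the list alone. Of the plasma cell list (adjusted p = 0.133), Tnfrsf13b, the receptor gene for BAFF and APRIL, rose by a log2 of 1.05, and Pou2af1 (-0.47), Ell2 (-0.42) and Edem1 (-0.25) were among 4 that fell. Of the apoptosis list (adjusted p = 0.0964), Bcl2 and Bmf (0.86) rose, and 10 of 12 members were not called. The NF-kB feedback list (adjusted p = 0.441) held 3 members that rose, Nfkbiz, Tnfaip8 (0.69) and Tnip1 (0.32), and 3 that fell, among them Tnfaip3 (-0.55). Zeb2 (0.62) and Fcrl5 rose among 17 members of the atypical memory list (adjusted p = 0.0796). Beside the fall of Mrc1, the myeloid marker list had a median of -0.36 (adjusted p = 0.0964) with 0 of 17 members called. Without deficient animal 1 it was called lower, at a median of -0.65 (adjusted p = 0.00336). With sex as a term it was at -0.13 (adjusted p = 0.707). Neutrophil markers, not called without the term (adjusted p = 0.784, median 0.08), were called higher with it (adjusted p = 0.00223, median 0.91). Camera with an estimated correlation, run only on all 13 libraries without added terms, gave adjusted p of 0.955 for myeloid and 0.977 for neutrophil markers.

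**Figure D3:**
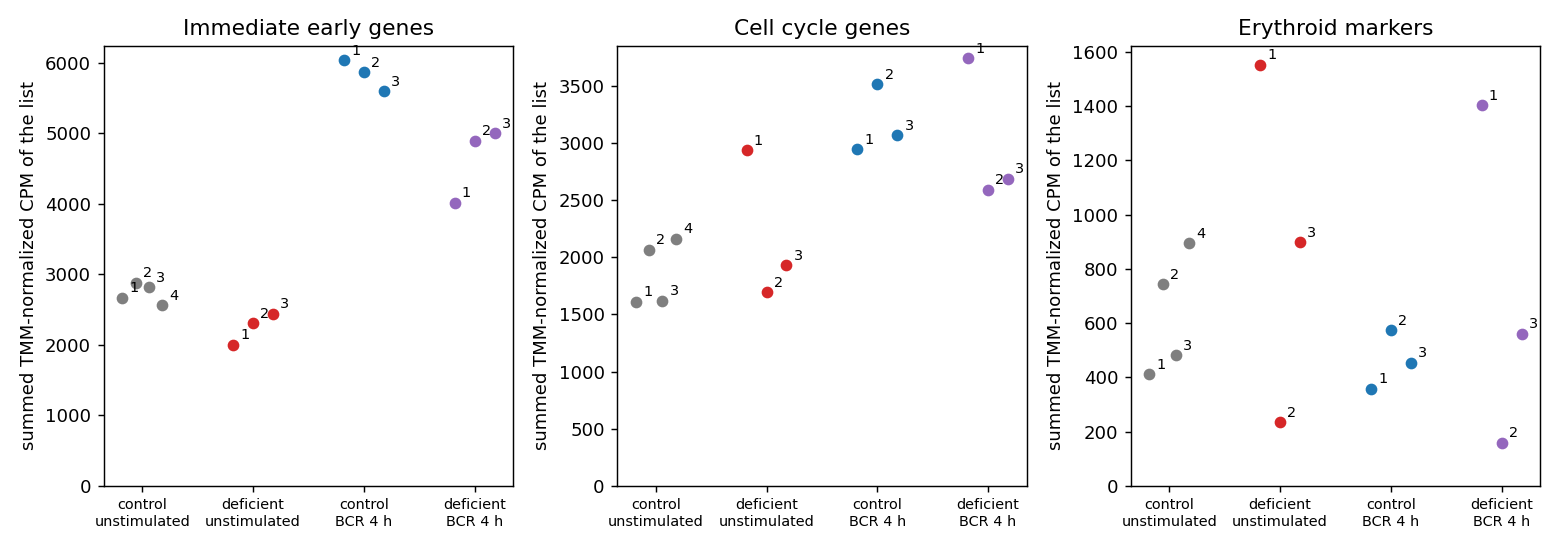
Summed TMM-normalized CPM of the immediate early, cell cycle and erythroid marker lists in each of the 13 libraries, with the library number beside each point. Deficient library 1 stands highest in the erythroid panel in both states, at 1552 and 1404 CPM, and highest in the cell cycle panel.

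Comparisons of stimulated with unstimulated cells do not separate the receptor from time in culture, since no time was given for unstimulated cells. In control cells the chemokine genes Cxcl10 and Ccl4 lay 22.1-fold and 16.0-fold higher after BCR stimulation. Ccl4 went from 14.1 ± 3.18 CPM (SD, n = 4) to 227 ± 26.6 CPM (n = 3). Interferon response genes rose alongside, Mx1 from 10.2 ± 2.96 to 144 ± 59.2 CPM and Ifit1 from 6.19 ± 1.91 to 96.3 ± 42.7 CPM. Cacna1i fell 18.9-fold, from 146 ± 15.9 to 7.75 ± 1.89 CPM, and Rasgrp2, a guanine exchange factor gene, fell from 272 ± 21.7 to 26.4 ± 5.24 CPM. Zc3h12a itself rose, by a log2 of 0.29 ± 0.07 (adjusted p = 0.00246).

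The test called 8191 of 13574 genes, 3873 higher and 4318 lower, with 1369 rising and 1681 falling by more than 2-fold. The median log2 change over genes was -0.13 with TMM, -0.06 with DESeq2's size factors and -0.20 with upper-quartile factors. Rises and falls are therefore relative to the scaling. Log2 changes were 4.46 ± 0.48 for Cxcl10 (chromosome 5, 92346638 to 92348889; adjusted p = 1.8e-05), 4.17 ± 0.27 for Lrrc32, 4.00 ± 0.32 for Ccl4, 3.95 ± 0.34 for Ifit1 and 3.82 ± 0.32 for Mx1. They were 3.76 for Ptgs2, which encodes a cyclooxygenase, 3.67 for Gng4 and 3.64 for Ifit3. Among the falls they were -4.24 ± 0.16 for Cacna1i (adjusted p = 1.3e-10), -4.12 ± 0.26 for B3gnt8 and -3.89 ± 0.20 for Spns2, a sphingosine 1-phosphate transporter gene. They were -3.70 for Ngfr, -3.55 for Tbxa2r, -3.36 for Fam101b, -3.36 for Rasgrp2 and -3.27 for Dmpk. Of the called genes 7919 had no overlap between the groups, against 63.47% of tested genes and 2 of 35 orderings by chance. Against a minimum fold of 1.5 the count was 3769.

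Ribosome biogenesis genes rose as a group in control cells: all 27 members rose, over all genes and adjusted over the list alone, with a median log2 change of 1.93 (adjusted p = 2.3e-17; adjusted p = 0.429 with an estimated correlation). Ncl went from 1204 to 5052 CPM and Nop16 from 34.7 to 153 CPM. Of 25 interferon response genes 22 rose, 1 fell and 2 were not called, the same adjusted over the list alone (median 2.24, adjusted p = 8.7e-07; adjusted p = 0.626 with an estimated correlation). In the activation surface list 16 of 22 rose and 1 fell, the same adjusted over the list alone, among them Cd69 (2.65) and Cd83 (1.82) (adjusted p = 1.8e-06; adjusted p = 0.193 with an estimated correlation). Cholesterol synthesis genes rose in 17 of 20 cases, with 1 falling, or 17 and 2 adjusted over the list alone, Idi1 by 2.07 (adjusted p = 4.5e-05; adjusted p = 0.626 with an estimated correlation). Resting B cell genes went down, 16 of 20 falling and 1 rising, the same adjusted over the list alone, with Cdkn1b at -1.88 and Ypel3 at -2.16 (adjusted p = 4.5e-05; adjusted p = 0.317 with an estimated correlation).

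Of immediate early genes in control cells 15 of 22 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.00138; adjusted p = 0.626 with an estimated correlation), Bhlhe40 by 2.26, while Btg2 (-1.62) and Id3 (-2.33) fell. Of endoplasmic reticulum stress genes 14 of 20 rose and 3 fell, the same adjusted over the list alone, Hspa5 by 1.47 (adjusted p = 0.00138; adjusted p = 0.486 with an estimated correlation). Known Regnase-1 targets rose in 11 of 18 cases with 1 falling, the same adjusted over the list alone, Nfkbiz by 1.76 and Nfkbid by 2.20 (adjusted p = 0.00141; adjusted p = 0.193 with an estimated correlation). Cytokine genes rose in 13 of 24 cases with 2 falling, the same adjusted over the list alone, Ccl3 by 3.29, while Ltb fell by 2.62 on the log2 scale (adjusted p = 0.00637; adjusted p = 0.429 with an estimated correlation). Of NF-kB feedback genes 11 of 18 rose and 7 fell, the same adjusted over the list alone, with Tnfaip3 at 2.42 (adjusted p = 0.0279; adjusted p = 0.626 with an estimated correlation). Heat shock genes rose in 8 of 12 cases with 3 falling, the same adjusted over the list alone, Hspd1 by 1.99 (adjusted p = 0.0166; adjusted p = 0.626 with an estimated correlation). Of 13 MHC class II presentation genes 10 fell and 3 rose, the same adjusted over the list alone, H2-DMa by -1.45 (adjusted p = 0.0114; adjusted p = 0.626 with an estimated correlation). B cell identity genes fell in 13 of 23 cases with 7 rising, the same adjusted over the list alone, Cd79a at -2.10 and Syk at -2.21 (adjusted p = 0.0445; adjusted p = 0.927 with an estimated correlation), and this call ended without control unstimulated library 2 (adjusted p = 0.0597). Myeloid markers were called lower only with the animal as a block (adjusted p = 0.0251; adjusted p = 0.385 without it).

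In deficient cells Cxcl10 lay 27.3-fold higher after BCR stimulation, rising from 2.91 ± 1.02 CPM (SD, n = 3) to 81.7 ± 38.5 CPM (n = 3). Mx1 rose 18.1-fold, from 10.8 ± 1.03 to 196 ± 48.7 CPM. Cacna1i fell 39.9-fold, from 126 ± 16.0 to 3.15 ± 0.385 CPM. Zc3h12a, at a log2 change of 0.04 ± 0.08, did not pass the test (adjusted p = 0.695). The test called 7856 of 13574 genes, 3841 higher and 4015 lower, with 1328 rising and 1586 falling by more than 2-fold, and 3489 against a minimum fold of 1.5. Here too the median log2 change over genes depended on the scaling. It was -0.11 with TMM, -0.07 with DESeq2's size factors and -0.20 with upper-quartile factors. Of the called genes 7546 had no overlap between the groups, against 61.99% of tested genes and 10% by chance. Log2 changes were 4.77 ± 0.56 for Cxcl10, 4.18 ± 0.36 for Mx1, 4.06 ± 0.38 for Ifit1, 4.04 for Ccl4, 4.03 for Ifit3, 3.73 for Ifit2, 3.72 for Lrrc32 and 3.70 ± 0.78 for Irg1, an itaconate-producing enzyme gene. The falls were -5.32 ± 0.18 for Cacna1i (adjusted p = 7.8e-11), -4.48 ± 0.27 for B3gnt8, -4.15 for Spns2, -3.97 for Ngfr, -3.57 for Tbxa2r, -3.56 for Rasgrp2, -3.52 for Zfp831 and -3.39 for Dmpk.

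The 13 lists called in deficient cells were those called in control cells, with the same directions. All 27 ribosome biogenesis genes rose, over all genes and adjusted over the list alone (median 1.87, adjusted p = 3.1e-17; adjusted p = 0.373 with an estimated correlation). Interferon response genes rose in 22 of 25 cases with 1 falling, the same adjusted over the list alone, Ifit2 by 3.73 (adjusted p = 2.9e-07; adjusted p = 0.563 with an estimated correlation). Immediate early genes rose in 16 of 22 cases with 2 falling, the same adjusted over the list alone, Bhlhe40 by 1.95 and Atf3 by 2.06 (adjusted p = 0.00212; adjusted p = 0.563 with an estimated correlation). Resting B cell genes fell in 16 of 20 cases with 2 rising, the same adjusted over the list alone, Ypel3 at -2.12 (adjusted p = 3.8e-05; adjusted p = 0.306 with an estimated correlation). Activation surface genes rose in 16 of 22 cases with 2 falling (adjusted p = 4.1e-06; adjusted p = 0.260 with an estimated correlation), cholesterol synthesis genes in 17 of 20 with 0 falling (adjusted p = 2.0e-05; adjusted p = 0.610 with an estimated correlation) and Regnase-1 targets in 10 of 18 with 0 falling (adjusted p = 0.00306; adjusted p = 0.260 with an estimated correlation), each the same adjusted over the list alone. Endoplasmic reticulum stress genes rose in 14 of 20 cases with 1 falling (adjusted p = 0.00018; adjusted p = 0.373 with an estimated correlation), heat shock genes in 8 of 12 with 2 falling (adjusted p = 0.0151; adjusted p = 0.563 with an estimated correlation) and NF-kB feedback genes in 12 of 18 with 6 falling (adjusted p = 0.00929; adjusted p = 0.563 with an estimated correlation), each the same adjusted over the list alone. Cytokine genes rose in 14 of 24 cases with 3 falling, or 15 and 4 adjusted over the list alone (adjusted p = 0.0193; adjusted p = 0.563 with an estimated correlation). MHC class II presentation genes fell in 9 of 13 cases with 1 rising, or 10 and 3 adjusted over the list alone (adjusted p = 0.00989; adjusted p = 0.610 with an estimated correlation), and B cell identity genes fell in 13 of 23 with 6 rising, or 14 and 6 adjusted over the list alone (adjusted p = 0.0193; adjusted p = 0.765 with an estimated correlation). With the animal as a block, erythroid markers (adjusted p = 0.0308; 0.837 without it) and myeloid markers (adjusted p = 0.00822; 0.232 without it) were also called lower.

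**Figure D4:**
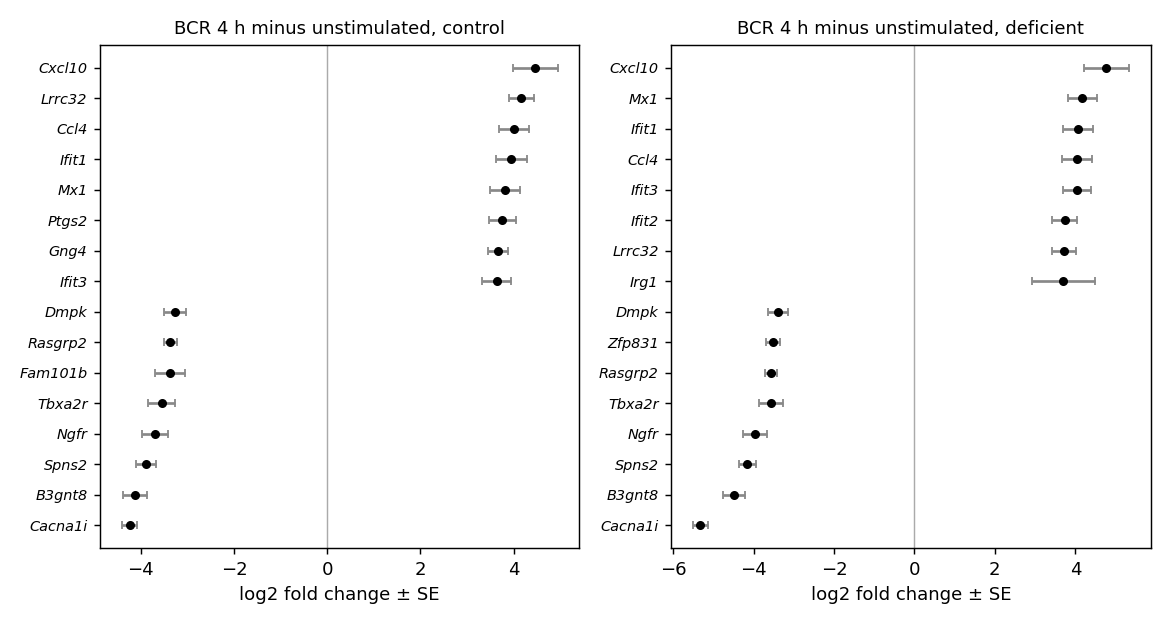
Log2 fold change after 4 h of BCR stimulation, with standard errors, for the 8 largest rises and 8 largest falls among the genes that met the naming rule, in control (left) and deficient (right) cells. Cxcl10 lies highest and Cacna1i lowest in both genotypes.

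Genes called in both genotypes after stimulation numbered 3521 among rises, against 1095.9 for independent lists of these sizes, and 3663 among falls, against 1277.2. Of genes called in both, 5 went opposite ways. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.90 and rho = 0.91.

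The response of Mapk3, which encodes the kinase ERK1, to the receptor differed between genotypes: it fell from 62.6 ± 1.98 CPM (SD, n = 4) to 23.2 ± 0.674 CPM (n = 3) in control cells and from 68.3 ± 5.66 to 43.5 ± 0.880 CPM in deficient cells (n = 3 each). The difference of responses was 0.78 ± 0.09 (SE) on the log2 scale (chromosome 7, 126759601 to 126765819; adjusted p = 0.00442), and Mapk3 was the 1 gene called. An unadjusted p under 0.05 was reached by 510 of 13574 genes, where 678.7 would be expected by chance, and DESeq2 called 48 genes. With the animal as a block, since library numbers pair the states within each genotype, 68 genes were called, 48 with a higher and 20 with a lower response in deficient cells. The blocked differences included Ppp1r3b at 1.17, Kctd14 at 0.93, Mapk3 at 0.77, Batf at 0.72 and Mllt6 at 0.67, and, below 0, Tnfrsf18 at -0.997, AA467197 at -0.82, Trib1 at -0.66, Il1r2 at -0.64 and Icam1 at -0.60. Of 31 lists 0 were called by camera without the block (fry 0), and 9 with it: endoplasmic reticulum stress, interferon response and glycolysis genes higher, and ribosome biogenesis, RNA decay, cytokine, Regnase-1 target, cell cycle and erythroid genes lower, although the medians without the block were above 0 for cell cycle (0.04) and erythroid genes (0.14). With an estimated correlation 0 lists were called (adjusted p = 0.985 for each of the 9, without the block). The count without the block was 12 with upper-quartile factors, 10 with no filter, 19 with sex as a term, 13 without deficient animal 1 and 22 with the erythroid marker level as a term. It was 4 without deficient unstimulated library 1, 3 without deficient unstimulated library 3, 2 without control stimulated library 2, 10 without deficient stimulated library 1 and 4 without deficient stimulated library 2.

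The genes called between genotypes in both states were 12 of 17 unstimulated and 102 stimulated rises, against 0.128 for independent lists, and 22 of 27 and 171 falls, against 0.340. 0 genes were called in opposite directions. The same animals supplied both states, so the lists are not independent even without an effect, and the values for independent lists leave this out. Exchanging genotypes among the 6 paired animals in all 20 ways, a test added after the data were seen, gave 34 genes called the same way in both states for the real grouping and 0 to 7 for the others (exact one-sided permutation p = 0.05, the smallest possible). In 1 of the others, which set all male against all female animals, 7 of 8 unstimulated calls were shared, so that grouping contrasted the sexes. Among the shared rises were Nfkbiz and Batf, and among the shared falls were Zbtb46 and Pou2af1. Across 13574 genes the unstimulated and stimulated effects correlated with r = 0.29 and rho = 0.36, and across 9779 genes with a mean log2 CPM of at least 2 with r = 0.66 and rho = 0.53; genes are not independent replicates. Exchanging genotypes among animals in all 20 ways gave r across the 13574 genes from 0.239 to 0.566 (exact one-sided permutation p = 0.75 for r and 0.15 for rho; the smallest possible is 0.05). The correlation across all genes was thus not distinguishable from that of the other groupings, of which the one by sex gave the highest r. The r of 0.66 was not put to this exchange.

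Unstimulated deficient cells were compared with control cells along the BCR response, with the control libraries split so that no library served both sides. The mean correlation across 13574 genes over the 6 splits was -0.056, with splits from -0.14 to 0.031, against -0.0012 on average in 100 simulations without effect, which ran from -0.031 to 0.027. Without the split it was 0.063, where the shared controls alone gave 0.14 on average. The split covariance was -0.0187 against a simulated -4e-04. Control animals with libraries in both states still stood on both sides of a split, and their libraries deviated together, while the simulation drew libraries independently, so no difference from the simulated values can be read.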

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

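The tests of the cell cycle list against deficient animal 1 and against sex were chosen after the result was seen, and the fits with the erythroid marker level as a term or without deficient animal 1 were added after the data were seen.

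Of 79 list levels and named-gene levels scanned in the 4 control unstimulated libraries, 2 held a library far from the others, against 3.95 expected, since chance marks about 1 in 20. The germinal centre list summed to 379 CPM in control unstimulated library 4. The heat shock list summed to 2610 CPM in control unstimulated library 2. The fall of Mapk3 after BCR stimulation differed between genotypes by a log2 of 0.78, in the test of the difference itself.

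The first pattern is the set of 44 genes changed in unstimulated deficient cells, which includes Nfkbiz, Pou2f2 and Pou2af1. Of the 35 splits of the 7 unstimulated libraries, 1 called as many genes, the real one, a share of 2.86%, and the highest other split called 2. This argues against chance but does not exclude it. Stimulated libraries kept their labels and shared the estimate of spread, and the split of male against female libraries called 0 genes. Other splits could thus call few genes. With sex as a term the called genes' median log2 change, in the direction of their call, was 0.49, with a spread of 0.0114, against 0.47 without it. The genes were picked from the same data, so this value could hardly fall and does not test sex. All 44 had no overlap between the groups, but so had all 273 genes called in stimulated cells. Lack of overlap thus came with the call and does not test sex either. An effect of genotype stays a hypothesis, and sex and other differences between the animals stay open.

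Another pattern is the lower immediate early list, with Fos, Junb and Dusp1. Of the 35 splits, 1 gave a list median as far from 0, the real one at a size of 0.325, where the highest other gave 0.319. The margin was narrow, and this list had the smallest camera p of the 31 lists in this comparison, so chance was not excluded. With the erythroid marker level as a term the median was -0.32 (spread 0.0888). That level, in mean log2 CPM, was 6.74, 4.04 and 5.78 in deficient and 4.78 to 5.87 in control unstimulated libraries. With such overlap the term had little room to move the median, and it covers no other precursors. Blood cell precursors thus stay open as a cause of the lower immediate early list. Without both libraries of deficient animal 1 the list median was -0.21, so part of its size came with that animal. The heat shock and handling list had a median of -0.03 (adjusted p = 0.81), and no test here separated cell handling from genotype, so that stays open.

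The last pattern weighed is the higher cell cycle list, with Tyms at 0.70, whose median without both libraries of deficient animal 1 was -0.020 (spread 0.161) against 0.37 with them, as an origin in that animal alone would need. With the erythroid marker level as a term it was 0.21 (spread 0.154), too close to 0.5 of the value without the term for that spread to decide, so blood cell precursors stay open. With sex as a term it was 0.60 (spread 0.202), but deficient animal 1 was the only deficient female, so this does not test sex apart from that animal. Whether CD43 selection removes such precursors was not tested. As group means, Slc4a1 and Car2 stood at 295 and 107 CPM in control against 415 and 164 CPM in deficient unstimulated cells. By library the erythroid list summed to 1552, 235 and 898 CPM in deficient and 412 to 895 CPM in control unstimulated cells. Precursor cells in the deficient animal 1 libraries may thus be a source. By camera the erythroid list was called higher with sex as a term (adjusted p = 0.00253, median 0.87) but not without it (adjusted p = 0.421, median 0.49). Without both libraries of deficient animal 1 its median was -0.24 (camera, adjusted p = 0.173).

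Of the 10 splits of the stimulated libraries, 1 called as many genes as the 273 of the real split (highest other 2), but 10 splits are too few for a share under 0.05. The 10 splits of the deficient libraries by stimulation are likewise too few, with 7856 genes in the real split and 0 in the highest other, 1 calling as many. For stimulation in control cells 1 of 35 splits, the real one, called as many as 8191 genes, a share of 2.86%. The highest other split called 4501. Control libraries 1 to 3 pair across states and many of these splits break the pairs, so that share does not measure chance. The splits that set 3 unstimulated libraries against the stimulated ones and 1 unstimulated called 2866 to 4501, so they still follow stimulation, a structure of the samples. Among the 8 that part as many pairs the highest other called 4433, and 8 splits are too few for a share under 0.05. For the difference of responses 2 of 20 relabellings called as many as 1 gene. The other of these, at 1, exchanged the genotypes of all 6 paired animals and so nearly mirrors the real grouping, with control animal 4 alone keeping its label, and the remaining ones called 0. With the animal as a block 1 of 10 called as many as 68, with the highest other at 29. These relabellings are too few for a share under 0.05.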

How the results depend on the processing

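The fits without deficient animal 1, with the erythroid marker level as a term and with sex as a term for lists are tests chosen after the data were seen. The genes picked by the naming rule kept direction in all 1206 combinations of gene, comparison and setting. Of these 1102 stayed on the same side of the threshold and 104 lost the call, 25 of them against a minimum fold of 1.5. Fitting only the 2 groups compared ended 6 of 16 calls for unstimulated deficiency and 5 of 16 for stimulated deficiency. The main fit takes its spread from all 13 libraries, and those of the other state pair with these by number. All 590 combinations for stimulation kept both direction and call. Between groups the rule asked for no overlap, so leaving out a library could hardly turn a direction. Other genes in the text were not part of this count. Counts changed by over 1.5 times as follows, and the cause was not tested unless the setting tests fewer libraries or a larger effect. In unstimulated cells, against 44 genes, the deficiency count was 70 with upper-quartile factors, 198 with sex as a term, 2 against a minimum fold of 1.5, 163 in DESeq2, 74 without deficient animal 1, 75 with the erythroid level, and 17 to 46 without single libraries. In stimulated cells, against 273, it was 511 with sex, 12 against the minimum fold, 532 in DESeq2 and 129 to 230 without single libraries. For stimulation the minimum fold gave 3769 genes in control and 3489 in deficient cells. For the difference of responses, against 1, it was 12 with upper-quartile factors, 10 with no filter, 68 with the animal as a block, 19 with sex, 0 against the minimum fold (DESeq2 48), 13 without deficient animal 1, 22 with the erythroid level and 1 to 10 without single libraries.

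Zc3h12a in unstimulated cells was at -0.38 with sex and -0.31 in DESeq2, both past the threshold, and -0.40 to -0.25 without single libraries. In stimulated cells it was at -0.58 against a minimum fold of 1.5, not past it. List calls fell to 0 in each comparison with an estimated correlation. Fry called 3, 3, 20 and 20 lists where camera called 7, 9, 13 and 13, and sex as a term gave 12 for unstimulated deficiency. In unstimulated cells that term added erythroid and neutrophil markers and interferon response genes (higher) and MHC class II presentation and RNA decay genes (lower). In stimulated cells it added neutrophil markers and atypical memory genes (higher) and MHC class II presentation genes (lower), and ended the cytokine call. For the difference of responses 9 lists were called with the animal as a block, 2 with the erythroid level and 3 without deficient animal 1. The unstimulated cell cycle list was no longer called without deficient library 1 (adjusted p = 0.935), nor the stimulated one without deficient animal 1 (adjusted p = 0.998, median 0.017). The sign of the test turned in both, but at such p-values no reversal is shown. The correlation of the deficiency with the BCR response over control splits went from -0.14 to 0.031, so its sign depended on the split. The correlation of the deficiency effects between states was 0.66 at a mean log2 CPM of at least 2, against 0.29. With the replicate number as a block, which pairs states within a genotype but not genotypes, deficiency counts were 37 and 274, and list calls 8 and 10. The lists added were interferon response, higher in unstimulated cells (adjusted p = 0.0490 against 0.155), and myeloid markers, lower in stimulated cells (adjusted p = 0.0222 against 0.0964). Beyond the values given above it changed no call of a named gene except those of Zc3h12d, Fcgr2b, Eng and Cdk5r1 in unstimulated deficiency, which ended. The alternative without immunoglobulin genes was not run, since no such gene was tested. Depth limits the lowest genes, since 3 counts stood for up to 0.140 CPM.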

Other observations

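Slit3, chosen after its values were seen and below the level of the naming rule, was higher in deficient cells by a log2 of 3.20 ± 0.30 (SE, adjusted p = 9.7e-05) unstimulated and 3.47 ± 0.34 (adjusted p = 4.5e-05) stimulated. It had 6 to 15 counts in the 7 control libraries and 82 to 138 counts in the 6 deficient libraries. Among genes called the same way in both states, also picked after their values were seen, were Sh3bp5 (0.50 and 0.59), Fcgr2b (0.54 and 1.03), Samsn1 (-0.34 and -0.68) and Rgs2 (-0.42 and -0.67), unstimulated and stimulated, in edgeR's test.

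Pou2f2 rose (0.69 and 0.72) while its coactivator Pou2af1 fell (-0.69 and -0.47) in both states. The plasma cell list, which holds Pou2af1, was not called with all 13 libraries (adjusted p = 0.0753 unstimulated and 0.133 stimulated), and was called lower without deficient animal 1 (adjusted p = 0.000981 and 0.0224). Camera with an estimated correlation, run only with all 13 libraries, gave adjusted p of 0.605 and 0.66. The list summed to 2976 to 3189 CPM in control and 2422 to 2609 CPM in deficient unstimulated libraries, and to 4515 to 4909 against 3743 to 4125 CPM after stimulation. Pou2af1 alone, at 1255 against 777.5 CPM, made up most of the unstimulated gap.

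By Xist and Y-linked genes, control libraries 1 were male and 2 to 4 female, and deficient libraries 1 were female and 2 and 3 male, alike in both states. Of the female libraries, control unstimulated library 2 held 71 counts of the Y gene Ddx3y and control stimulated library 3 held 59, while the others held 0 or 1. Deficient unstimulated library 2, otherwise male, held 335 counts of Xist, against 5 in its stimulated counterpart.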
